A study of Mus musculus with 2 samples.

How the data were processed

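Innate lymphoid cells (ILCs), lymphocytes without a rearranged antigen receptor, were sorted from mouse skin at postnatal day 1 and postnatal day 14, with 1 library of each day in the labels. Per the labels' protocols, skin was digested with collagenase and CD45+, lineage-negative, Thy1.2+ cells were sorted and captured with the 10x Genomics 5' kit. The deposited table holds UMI counts of 18786 gene symbols in 5246 cells, whole numbers that had not been scaled. A UMI is a molecular tag that lets copies of the same RNA molecule be counted once. Per the submitters' processing notes, Cell Ranger 3.1.0 and Seurat 4.1.0 were used with the mm10 build, and their settings are not given in the sources used here. The cell with the fewest UMIs held 500, and no cell held fewer than 211 genes.

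Cell names end in a suffix that divides them into 2 sets, called cell set 1 and cell set 2 here. The suffix matches neither day's label, and no cell was assigned to a day from its expression. The table was therefore treated as 1 pooled sample. The days were not compared, and wherever a comparison of the days had been planned, the values of both cell sets stand side by side. A ratio between the sets describes these 2 sets of cells and carries no replicate error. The 16-base barcodes did not repeat within a set, and 4 of them occurred in both sets.

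Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, which left out 30 cells of set 1 and 267 of set 2. Scrublet, run within scanpy 1.11.5 on each set by itself, called 7 doublets in set 1 and 0 in set 2, which is 0.141% of the 4949 cells it was given. These 7 were removed as planned, although so low a share points to doublets left undetected. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5 gave 7 clusters of 4942 cells.

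Clusters were named from 18 marker lists fixed before the data were examined, while the naming rule was set after the clusters had been seen. A marker counted as raised at 20 CPM or more, 2-fold over the other cells and with a UMI in at least 10% of the cluster's cells. A cluster with 4 or more raised cycling markers was called cycling. A cluster with at least 4 raised markers of another type, more than of ILC2, took that type's name only with 2 more raised markers than the next type and more of its own markers than of any other type among its 10 leading genes. Otherwise it stayed unnamed. ILC2-like clusters needed 5 ILC2 markers at 50 CPM or more, more than of any other type, and a median log2 ratio of the ILC2 markers above -1. Clusters whose median UMI count fell below 0.333 of their set's, with no ILC2 marker among the leading genes, stayed unnamed.

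For each set, the UMIs of a gene were summed over cells and given per 1000000 UMIs of the set as CPM, with exact Poisson 95% intervals. The interval of a ratio came from the exact binomial interval of set 2's UMIs among those of both sets. Shares of cells carry exact Clopper-Pearson 95% intervals. All of these cover counting error only, and a count of 0 was taken to allow up to 3 UMIs. Set 1 held 16400074 UMIs over its kept cells and set 2 18026148, so a gene at 10 CPM had well over 100 UMIs in each.

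Named genes followed a rule fixed before the data were examined. It took the 10 largest and the 10 smallest ratios of CPM + 10 over all kept cells and within the largest class, and 5 of each in other clusters. A gene needed at least 100 UMIs over both sets. Ribosomal protein, mitochondrial, haemoglobin, antigen receptor, Xist, Y-linked and unnamed gene models were left out. Up to 4 members of each of 16 gene lists with at least 50 UMIs were named by the size of their ratio. Markers named beside these were taken from the marker lists, and a few genes that the rule picked are not given in the text. Because the ILC2-like cluster 4 had Ccr7, listed as a dendritic cell marker, and no ILC2 marker among its 10 leading genes, ILC2-like cells did not meet the condition for a comparison as a class and were compared by cluster number, with cluster 0 of set 1 beside cluster 4 of set 2.

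The median log2 ratio of each list (CPM + 1, members with at least 20 UMIs) was placed among 10000 random lists of the same size, each member drawn from the 100 genes nearest in expression. A list was said to stand apart outside the 2.5th to 97.5th percentile, as a description of these cell sets. TMM factors came from edgeR 4.0.16 and were used only as another scaling, which moved the median gene by 0.15 (log2) over all kept cells and by 0.20 between the ILC2-like clusters. For cycling cells, each cell was thinned to 4106 UMIs, the lower quartile, which left out 63 cells of set 1 and 1172 of set 2.

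Ratios and list percentiles were run on simulated counts with known changes, drawn for each gene independently from the Poisson model that the intervals assume. Such counts cannot show how the intervals and percentiles hold for UMIs clumped in single cells or for genes that vary together. Over all kept cells (9481 genes), 95.4% of the intervals of unchanged genes held a ratio of 1, and the median ratio found for genes simulated at 4 was 4.01. Of 200 unchanged lists, 4.5% fell outside the limits. Gene positions are from GENCODE M21 on GRCm38 (mm10), in which 98.8% of the table's symbols were found. Alternatives fixed before the data were examined covered the clustering settings, the scaling, thinning, doublets, cycling cells and the list settings. Subsets of cells by sex-linked RNA, removal of the cell with most UMIs of a gene, and other cycling measures were added after seeing the data.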

Results

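Single-cell expression was measured in ILCs sorted from the skin of C57/BL6 mice at postnatal day 1 and day 14, with 1 library of each day. The labels name both ages as the subject of the study. Cell set 1 held 1471 deposited cells with a median of 10577 UMIs and 2644 genes per cell. Cell set 2 held 3775 cells with a median of 4672 UMIs and 1505 genes. Which set came from which day was not assigned, so the values below describe the 2 cell sets and not the ages. There were no replicates, no test was run between the sets, and intervals are 95% intervals of counting error.

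ILC2-like cells made up the largest clusters of both cell sets, yet they lay in different clusters. Cluster 0 held 49.4% of set 1 (46.8 to 52.1%) and 0.827% of set 2 (0.554 to 1.19%). Clusters 3 and 4 held 28.0% and 57.8% of set 2 and 1.32% and 1.19% of set 1. Gata3, the transcription factor that ILC2s depend on, stood at 755 CPM in cluster 0 of set 1 and at 394 and 729 CPM in clusters 3 and 4 of set 2. Areg, which encodes the tissue-repair factor amphiregulin, reached 778, 825 and 1147 CPM in the same order. Il13 was at 244, 399 and 360 CPM, while Il5, an eosinophil growth factor, was at 201, 41.2 and 344 CPM. Of the 13 ILC2 markers, 8, 8 and 10 reached 50 CPM in these clusters. Il1rl1 and Klrg1 were at 8.97 and 2.10 CPM in set 2 outside a group of 72 cells described at the end. The median log2 ratio of the ILC2 markers to the other cells was -0.06, -0.44 and 0.54. The ILC3 markers raised in cluster 3, Ccr6 and Lta, were also those raised in cluster 5. Because clusters 0, 3 and 4 each came almost wholly from 1 set, a cluster and a library cannot be separated here, and their sizes are given as values.

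The ILC2-like clusters had different leading genes. Cluster 0 was led by Slc38a4, Igsf5, Calca and Hs3st1, with Ptgs2 and Hes1 among its 10 leading genes. Cluster 3 was led by the heat-shock genes Hspa1b and Hspa1a, the early-response gene Fosb, and Id3, Il2 and Tnfsf9. Hopx, Ccr7, Cd70 and Bcl2a1b led cluster 4. Fosb had a UMI in 86.5% of the cells of cluster 3, and Hspa1a in 68.8%.

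Il22, the cytokine by which type 3 lymphocytes act on epithelium, marked cluster 1, which held 10.6% of set 1 (9.05 to 12.3%) and 0.171% of set 2 (0.0628 to 0.372%). The 6 ILC3 markers raised there were Il23r, Il22, Cd4, Tmem176a, Tmem176b and Il1r1, beside 5 ILC precursor markers, Zbtb16, Tcf7, Pdcd1, Cd7 and Itga4. Il22 UMIs were found in 25.3% of the cells of cluster 1. Fcer1g, Tyrobp, Car2, the haemoglobin gene Hbb-bs (784 CPM against 65.2 CPM in other clusters) and the MHC class II gene H2-Ab1 were among its leading genes. The cluster stayed unnamed, while the same rule called its counterparts at resolution 1.0 and at a limit of 5% mitochondrial UMIs ILC3-like, and at resolution 0.3 no such cluster appeared in either set. With set 2 clustered by itself the same rule called a cluster of 377 cells ILC3-like. Of these, 258 were cells of cluster 5, 102 of cluster 3 and 0 of cluster 1, and they held 2 UMIs of Il22. Over all kept cells the ILC3 marker list was higher in set 2 (median 0.94, percentile 100), with 8 of 12 measured members higher and 4 lower. Its members summed to 558 CPM in set 1 and 772 CPM in set 2.

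Cluster 5 held 12.5% of set 1 and 7.55% of set 2 and had little RNA of several ILC2 genes. Which set had the larger share of such clusters changed with the settings, with 12.3% and 27.7% at a limit of 5% mitochondrial UMIs and 22.0% and 22.9% with 15 principal components. Its cells had 124 CPM of Areg in set 1 and 82.6 CPM in set 2. Cd3g reached 859 and 1035 CPM there and Thy1, the gene of a sorting marker, 409 and 832 CPM. Over all kept cells Cd3g stood at 457 CPM in set 1 and 533 CPM in set 2, whereas Cd3e, another chain of the T cell receptor complex, was at 7.44 and 5.94 CPM and Trac at 10.6 and 19.5 CPM. Within cluster 5 Cd3e was higher, at 13.7 CPM in set 1 and 23.7 CPM in set 2, with Cd3d at 15.2 and 30.4 CPM. The alpha beta T cell markers as a list, which also holds Trbc1 and Trbc2, summed to 1260 CPM in set 1 and 1485 CPM in set 2. Of 10 measured members 7 were higher and 3 lower in set 2 (median 0.36, percentile 98.05). The gamma delta T cell markers, which also hold Cd3g, summed to 637 CPM in set 1 and 873 CPM in set 2. Of 11 measured, 6 were higher and 5 lower in set 2. Cluster 6, with a median of 1146.5 UMIs in its 84 cells, was led by Nabp1, Neat1 and Il18r1 and stayed unnamed.

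**Figure D1:**
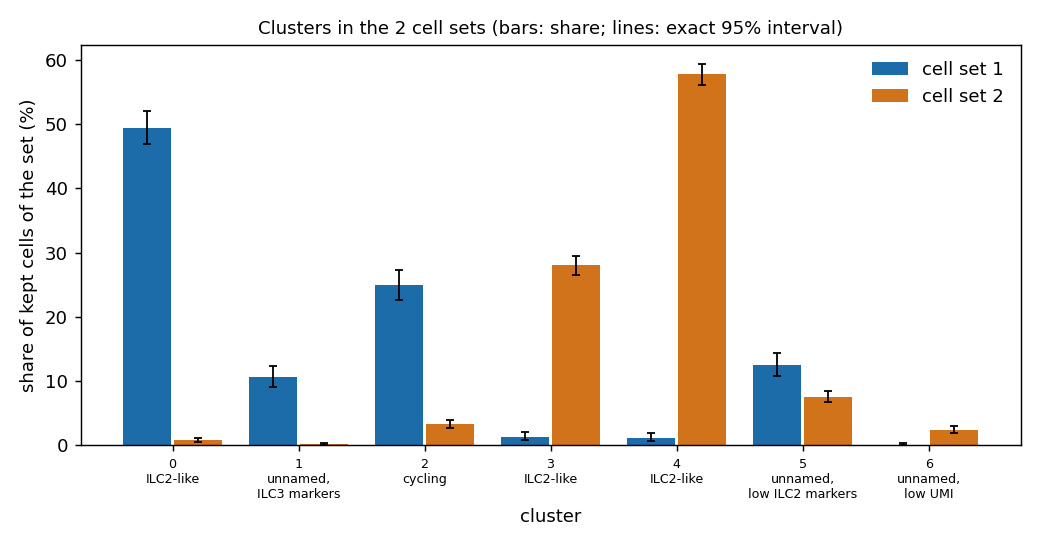
Share of the kept cells of each cell set (vertical axis, percent) in each of the 7 clusters (horizontal axis), with exact 95% intervals as lines. Cluster 0 held 49.4% of set 1, and clusters 3 and 4 held 28.0% and 57.8% of set 2.

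Cycling cells, marked by Mki67, Top2a and Birc5, made up 24.9% of set 1 (22.7 to 27.2%) and 3.34% of set 2 (2.77 to 3.98%). The planned measure, at least 3 UMIs of the S phase and G2M lists after thinning, did not separate the sets, with 92.6% of cells in set 1 and 90.5% in set 2. Most cells of both sets passed it. With at least 5 UMIs, the shares were 80.3% (78.1 to 82.4%) and 74.1% (72.3 to 75.9%), with intervals that did not meet. Cenpa, a gene of the G2M list, was also found outside the cycling cluster, at 151 CPM in cluster 0 of set 1 and 525 CPM in cluster 4 of set 2. With the 8 cycling markers alone, a measure added after seeing the data, 36.4% of the thinned cells of set 1 (33.8 to 39.0%) and 8.82% of those of set 2 (7.70 to 10.0%) had at least 3 UMIs. Without thinning these shares were 46.1% and 8.69%. Over all kept cells 21 of 22 S phase genes and 22 of 23 G2M genes had lower CPM in set 2, with list medians of -1.62 and -1.96 (log2, set 2 over set 1).

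Over all kept cells, Il22 and a group of genes that led cluster 0 stood higher in set 1. Il22 (chromosome 10, 118204942 to 118210047, GRCm38) was at 166 CPM in set 1 and 3.77 CPM in set 2, a ratio of 44.1 (34.6 to 56.9), and 1 cell held 17.4% of its UMIs in set 1. Hes1, a target of Notch signalling (chromosome 16, 30064384 to 30067796), stood at 247 and 26.2 CPM. Ptgs2, which encodes cyclooxygenase-2 (chromosome 1, 150100031 to 150108227), was at 157.5 and 21.1 CPM. Slc38a4, an amino acid transporter gene, had 637 UMIs in set 1 and 5 in set 2. Rab27b, Pcsk1 and Gcsh were 10.6, 10.6 and 7.49 times higher in set 1. The histone genes Hist1h2ap and Hist1h2ae, made in S phase, were 16.1 and 5.23 times higher. Among cells of the ILC2-like clusters alone, which leaves out the cycling cluster, the difference of Hist1h2ae was 1.28 times on the scale of CPM + 10. Krt14, a keratin of basal epidermis, was at 51.1 CPM in set 1 and 2.05 CPM in set 2, and in set 1 it lay between 40.5 and 60.5 CPM in clusters 0, 1, 2 and 5 alike.

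Cd70 and Hopx stood furthest apart on the scale of CPM + 10 among the genes higher in set 2. Cd70, the ligand of the costimulatory receptor CD27 (chromosome 17, 57145997 to 57149777), was at 3.29 CPM in set 1 and 186 CPM in set 2, a ratio of 56.4 (43.1 to 75.2). Ccr7, a chemokine receptor used in migration to lymph nodes (chromosome 11, 99144196 to 99155077), stood at 41.0 and 377 CPM, and Cxcr4 at 72.3 and 507 CPM. Ramp1, a subunit of the receptor for the neuropeptide CGRP, was at 19.3 and 201 CPM, while Calca, the gene of CGRP itself, was at 630 CPM in set 1 and 155 CPM in set 2. Also higher were Hopx (50.4 and 509 CPM), Rnf208, Ctss, Ly6g5b and Sema6d, with ratios from 8.67 to 40.1. The 20 genes kept their direction under every scaling, thinning and subset of cells tried.

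**Figure D2:**
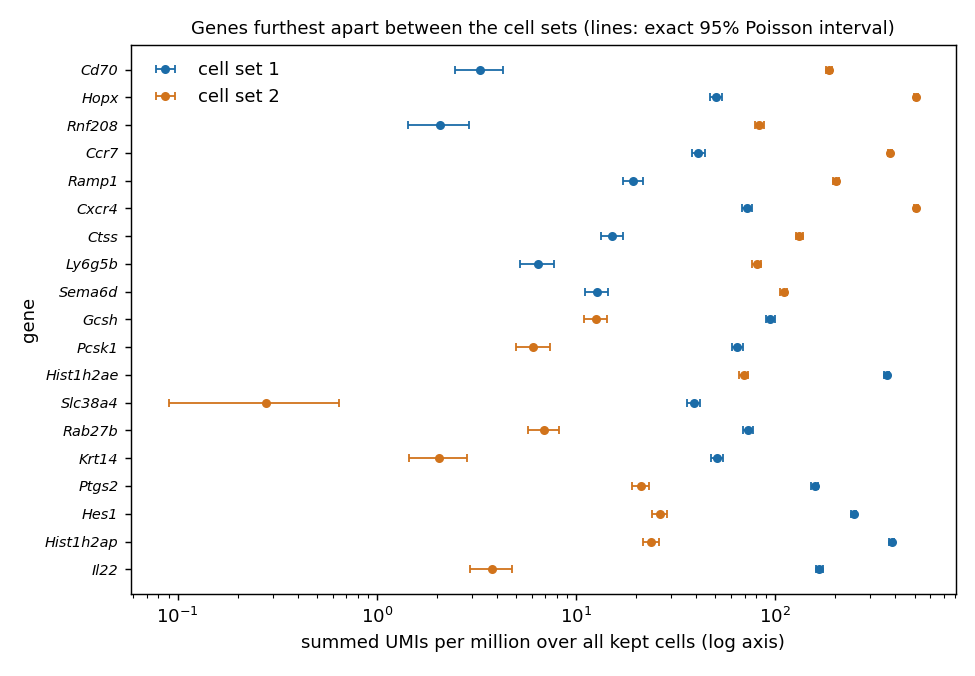
Summed CPM (horizontal, log axis) of 19 of the 20 genes furthest apart between the cell sets over all kept cells, with exact 95% Poisson intervals as lines. Il22 stands at 166 CPM in set 1 and 3.77 CPM in set 2, and Cd70 at 3.29 and 186 CPM.

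Effector genes did not move as a block. Of 11 type 2 effectors measured, 5 were higher and 6 lower in set 2, and their median of -0.09 lay at the 49.2 percentile of random lists. The median was 0.39 (percentile 98.9) in Xist-only and -0.70 (percentile 0.205) in Y-only cells, subsets chosen after seeing the data. Il5, Il13 and Csf2 had ratios of 1.66, 1.49 and 1.85, whereas Il4 was at 74.3 CPM in set 1 and 29.7 CPM in set 2. Among 8 type 3 effectors 4 were higher and 4 lower in set 2 (median 0.16, percentile 86.3), with Lta 3.25 and Il17f 2.53 times higher and Tnfsf11 at 80.4 and 35.7 CPM. Of 12 type 1 and cytotoxic effectors 7 were higher in set 2 (median 0.04, percentile 81.2). Gzmb, a granule protease, was at 8.72 and 44.1 CPM, while Gzma had 207 UMIs in set 1 and 0 in set 2, at least 75.8-fold lower.

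As lists over all kept cells, receptor, precursor and homing genes lay higher in set 2. Of 15 cytokine and alarmin receptors 12 were higher (median 0.62, percentile 99.97), with Il17rb, a receptor of IL-25, at 16.7 and 63.7 CPM and Il9r at 21.8 and 62.7 CPM. Of 14 ILC precursor genes 11 were higher (median 0.51, percentile 99.9), with Sox4, Tcf7 and Maf 2.59, 2.25 and 2.13 times higher, against Itga4 at 75.5 and 31.2 CPM. Of 16 homing and residency genes 11 were higher (median 0.54, percentile 99.99), among them Ccr6, 5.25 times higher, and Itgae, the gene of an integrin that binds epithelium, 4.46 times higher. Of 12 checkpoint and neuroimmune receptors 8 were higher (median 0.20, percentile 95.2), led by Ramp1, while Cd200r1 stood at 82.0 and 32.8 CPM. Thy1 itself was at 211 CPM in set 1 and 493 CPM in set 2. By cluster, receptors summed to 1728 CPM in cluster 0 of set 1 and 1806 and 3074 CPM in clusters 3 and 4 of set 2. Precursor genes (2126, 3353 and 3795 CPM) and homing genes (5577, 6274 and 7109 CPM) were higher in both clusters of set 2. Malat1, a nuclear RNA, was at 11143 and 22531 CPM in the kept cells of sets 1 and 2. Receptors, precursor and homing genes each summed highest in cluster 6, which had Malat1 among its leading genes, and a link was not tested.

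Fetal and neonatal genes lay lower in set 2, at a median of -1.37 over 11 members (percentile 0), of which 9 were lower. With CPM + 10 the median was -0.26 (percentile 0.46). Igf2bp3, which binds RNA in fetal tissues, was at 44.9 and 16.3 CPM, and Arid3a at 33.0 and 12.1 CPM. H19, an imprinted RNA, had 170 UMIs in set 1 and 0 in set 2, at least 62.3-fold lower, while Plagl1 was 2.20 times higher in set 2. Like Krt14 and Cma1 of other skin cells, H19 lay at similar levels in clusters 0, 1, 2 and 5 of set 1 (7.32 to 14.4 CPM), so RNA from outside the ILCs is not excluded for it. Glycolysis and oxidative phosphorylation each had 12 of 14 genes lower in set 2, with medians of -0.30 and -0.27 at percentiles 5.65 and 5.96. The median gene with at least 100 UMIs was itself lower in set 2 (-0.14), and with TMM scaling these list medians were -0.15 and -0.12. Uqcrc1 was at 89.3 and 42.9 CPM and Tpi1 at 283 and 134 CPM. Lipid handling genes had 9 of 13 lower (median -0.41, percentile 5.07), with Pparg at 17.9 and 2.44 CPM and Dgat2, an enzyme of triglyceride synthesis, 6.93 times higher in set 2.

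Interferon response genes were lower in set 2 in 10 of 12 members (median -0.57, percentile 2.10), with Bst2 at 78.1 and 46.6 CPM. The median moved to -0.35 (percentile 15.9) in thinned cells. MHC class II genes had a median of 0.53 (percentile 99.0) with 4 of 7 higher, which turned to -1.45 with members of at least 100 UMIs. Cd74, the invariant chain, was 3.09 times higher in set 2, while H2-Aa, H2-Ab1 and H2-Eb1 were at 15.7, 14.9 and 15.4 CPM in set 1 and 4.33, 4.22 and 5.77 CPM in set 2. H2-Aa stood at 159 CPM in cluster 1 of set 1 against 2.75 CPM in its cluster 0. In the cycling cluster H2-Aa went the other way, and 4 of 4 MHC class II genes measured, H2-Aa among them, were at least 2-fold higher in set 2 (percentile 100). This rests on few UMIs, since the whole list held 183 there in set 1 and 175 in set 2, of which Cd74 held 92 and 94. Early-response genes had 10 of 17 higher in set 2 (median 0.21, percentile 95.1), with Fosb 2.97 times higher and Atf3 at 880 and 370 CPM. In thinned cells the median of this list was -0.10 (percentile 22.9).

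**Figure D3:**
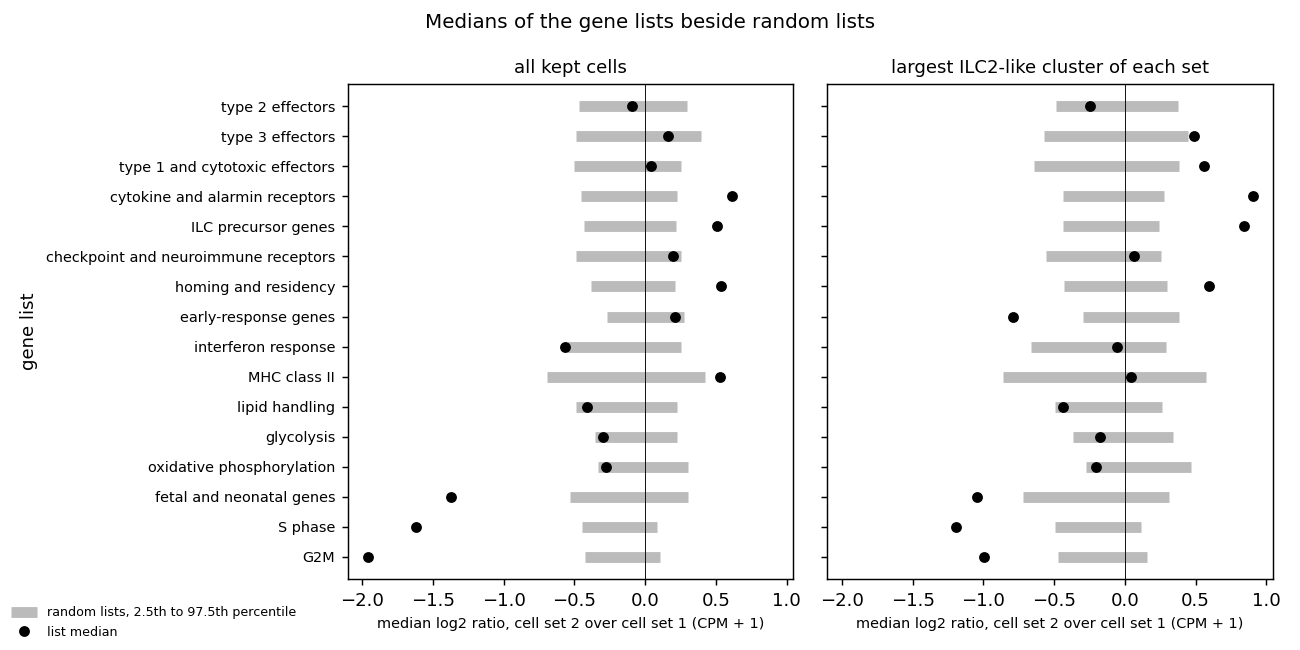
Median log2 ratio of set 2 over set 1 (horizontal axis, CPM + 1) of each of the 16 gene lists (points) beside the central range of random lists (grey bars), over all kept cells and between cluster 0 of set 1 and cluster 4 of set 2. The G2M list lies at -1.96 and the cytokine and alarmin receptors at 0.62 over all kept cells.

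Between cluster 0 of set 1 (709 cells) and cluster 4 of set 2 (2026 cells), many of the same genes stood apart, and several of them also led these clusters. They were compared by number and not as a class, since the leading genes of cluster 4 held the dendritic cell marker Ccr7 and no ILC2 marker. Hopx was at 24.2 and 751 CPM, Cd70 at 3.40 and 246 CPM and Ramp1 at 9.15 and 179 CPM. The MHC class I gene H2-Q7 and the cathepsin gene Ctsw were 13.0 and 11.9 times higher in set 2. Ctss, Bcl2a1b, Ccr7 and Rnf208 were also higher there. Higher in set 1 were Hes1 (293 and 24.8 CPM), Ptgs2, Rab27b, Gcsh, Hs3st1, Krt14 and Slc38a4, the last with 482 and 2 UMIs. Heat-shock genes also differed between these clusters, with Hspa1a at 855 and 95.9 CPM, Hspa1b at 849 and 152 CPM and Hspb1 at 150 and 8.96 CPM. Early-response genes as a list had a median of -0.79 (12 of 17 lower in set 2), with Jun at 318 and 67.4 CPM. Cells of set 2 rich in these RNAs lay in cluster 3 (2632 CPM of Hspa1a), so the low values of cluster 4 do not describe set 2 as a whole. Over all kept cells Hspa1a stood at 954 and 855 CPM and Hspa1b at 938 and 1115 CPM.

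Within these clusters the receptors (13 of 15 higher in set 2, median 0.90), the ILC precursor genes (10 of 14, median 0.84) and the homing genes (10 of 15, median 0.60) again lay above random lists. Cluster 4 held 57.8% of the kept cells of set 2, so these values are not independent of those over all kept cells. Whether the higher Malat1 of set 2 bears on these lists was not tested. Tcf7 was 3.70 times higher in set 2 and Pdcd1, the gene of the checkpoint receptor PD-1, 2.37 times, whereas Pdcd1 stood at 22.8 CPM in cluster 3 of set 2 against 58.0 CPM in cluster 0 of set 1. Fetal and neonatal genes lay lower (median -1.04, percentile 0.14), though inside the range of random lists with members of at least 100 UMIs (-0.57, percentile 8.28) and in Xist-only cells (-0.57, percentile 9.28). As a sum, these genes differed little, at 163 CPM in cluster 0 of set 1 and 153 CPM in cluster 4 of set 2. In cluster 3 of set 2 they summed to 103 CPM. Type 3 effectors were at a median of 0.49 (percentile 98.0) and type 1 and cytotoxic effectors at 0.56 (percentile 99.4), with Xcl1 8.26 and Gzmc 7.46 times higher and Gzma at 166 and 0 UMIs. The type 3 median moved inside the range of random lists in 4 alternatives, among them thinned cells (0.29), and the type 1 median turned to -0.0888 with no minimum of UMIs. The type 2 list did not stand apart (median -0.25, percentile 23.7), but did with no minimum (-0.59, percentile 0.53). Calca and Il4 stood at 924 and 87.1 CPM in set 1 and 209 and 21.2 CPM in set 2, and Csf2 and Il5 were 2.09 and 1.71 times higher in set 2. The S phase list was lower in set 2 (median -1.19), as were 19 of 21 G2M genes. The remaining lists had medians of -0.44 (lipid handling), -0.20 (oxidative phosphorylation), -0.18 (glycolysis), -0.06 (interferon response), 0.04 (MHC class II) and 0.07 (checkpoint and neuroimmune receptors), all inside the range of random lists.

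In the cycling cluster (357 and 117 cells), Hopx was at 11.1 and 375 CPM, Ccr7 at 18.1 and 335 CPM, Ramp1 at 9.20 and 168 CPM, Cxcr4 at 66.2 and 533 CPM and Ctsw at 30.8 and 281 CPM. Il22 had 652 UMIs in set 1 and 1 in set 2, a ratio of 133 (23.8 to 5271). This interval covers counting error only, and how the Il22 UMIs were spread over the cells of this cluster was not examined. Hes1 stood at 278 and 28.3 CPM, and Ptpn13, Rab27b and Pcsk1 were also higher in set 1. The S phase and G2M lists did not stand apart within this cluster (medians 0.10 and 0.05). Il4 was at 80.9 and 6.67 CPM there, and Calca at 521 and 90.8 CPM. The type 2 list had a median of 0.69 (percentile 99.99) with 6 of 10 members higher and 4 lower in set 2.

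In cluster 5 (179 and 265 cells), Atf3 was at 462 and 24.7 CPM, Tyrobp at 109 and 4.75 CPM and Ifitm2 at 87.3 and 2.85 CPM, with Pcsk1 and Epcam also higher in set 1. Genes higher in set 2 were Rnf208 and 4 keratin-associated protein genes of hair, Krtap8-1, Krtap3-2, Krtap4-2 and Krtap15. A single cell held 96.5% of the 1784 keratin-associated UMIs of set 2 in this cluster. Receptors were higher in set 2 (median 0.74, 9 of 11), with Il9r at 38.7 and 124 CPM, and type 2 effectors lower (median -0.59, 6 of 9 lower), with Csf2 at 121 and 27.5 CPM. Interferon response genes lay at -1.30 (6 of 7 lower).

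Markers of other skin cells were present at low levels and differed between the sets. Fibroblast markers summed to 91.3 CPM in set 1 and 5.60 CPM in set 2, with Col3a1 at 31.0 and 0.444 CPM. Cma1, a mast cell protease gene, had 373 UMIs in set 1 and 0 in set 2, and in set 1 it lay between 19.1 and 29.5 CPM in clusters 0, 1, 2 and 5. Of 10 keratinocyte markers 8 were lower in set 2 (median -2.68, percentile 0), with Krt5 at 21.8 and 1.55 CPM, while Sfn stood at 84.9 and 226 CPM. B cell markers summed to 14.8 and 11.3 CPM. The macrophage marker Lyz2 had 5 and 3 UMIs. Erythroid markers summed to 128 and 210 CPM, with 4 of 4 measured members higher in set 2 (median 1.33, percentile 99.9), although Hbb-bs was highest in cluster 1 of set 1 (805 CPM).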

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

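Cells above 10% mitochondrial UMIs, which enter no comparison, held a signal of some lymphocyte genes, and this is why they are listed. They made up 2.04% of the deposited cells of set 1 and 7.07% of those of set 2. The 267 such cells of set 2 had a median of 898 UMIs, with Gata3 at 849 CPM, Rora at 2934 CPM and Il7r at 1390 CPM, against 593, 1768 and 851 CPM in the kept cells of that set. Other lymphocyte genes were lower in them, with Il5 at 68.5 CPM against 241 CPM, Areg at 438 CPM against 991 CPM and Thy1 at 161 CPM against 493 CPM, and Malat1, a nuclear RNA, was at 111894 CPM against 22531 CPM. In the 30 cells of set 1 Gata3 stood at 612 CPM against 577 CPM in the kept cells, Areg at 1673 CPM against 642 CPM, Il13 at 109 CPM against 243 CPM and Krt14 at 98.4 CPM against 51.1 CPM. No test was run on these cells, and no explanation was weighed.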

How the results depend on the processing

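The settings by sex-linked RNA, without the cell with most UMIs of a gene, and the cycling measures with the 8 markers or without 6 genes were chosen only after the result was seen. No paired analysis was possible because each label has 1 library and cells were not assigned to a day, and no sample was left out in turn for the same reason. Where a value below changed, the cause was not tested unless it is given.

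Over all kept cells 20 of 20 named genes kept their direction under each of the 10 alternatives, and 20 of 20 did so under each of the 8 run between the ILC2-like clusters. The smallest ratio over all kept cells, 1.21, was that of Hist1h2ae without cycling cells, which are the cells that make histone RNA. Of the log2 ratios of named genes under the alternatives, 1133 lay within the counting error of the planned value, 298 lay beyond it and 1 reversed a difference that counting error did not cover. This was H2-Aa, at 0.0386 (log2) among only cells of the ILC2-like clusters. That setting leaves out the cycling cluster and clusters 1, 5 and 6, and H2-Aa stood at 159 CPM in cluster 1 of set 1. Keeping the called doublets changed nothing between the ILC2-like clusters by construction, since those cells had no cluster.

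Of the list values, 199 kept their place inside or outside the range of random lists. A list inside that range could still change sign. Early-response genes over all kept cells went from 0.21 to -0.10 in thinned cells and -0.03 in Xist-only cells. Type 2 effectors went from -0.09 to 0.24 with members of at least 100 UMIs. Interferon response over all kept cells was weaker at -0.19 (CPM + 10), -0.25 (at least 100 UMIs), -0.35 (thinned), -0.39 (Xist-only) and -0.17 (Y-only). MHC class II was weaker at 0.0794 (CPM + 10) and reversed at -1.45 (at least 100 UMIs), -1.74 (thinned), -1.97 (Xist-only) and -0.12 (Y-only). Lipid handling stood apart with TMM scaling (-0.35), checkpoint and neuroimmune receptors in Xist-only cells (0.29), and type 2 effectors in Xist-only (0.39) and, the other way, in Y-only cells (-0.70).

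Between the ILC2-like clusters type 3 effectors were weaker at 0.23 (CPM + 10), 0.32 (at least 100 UMIs), 0.29 (thinned) and 0.0113 (Y-only). Fetal and neonatal genes were weaker at -0.57 with at least 100 UMIs and at -0.57 in Xist-only cells. With no minimum, type 1 and cytotoxic effectors reversed to -0.0888 and type 2 effectors stood apart at -0.59. Checkpoint and neuroimmune receptors stood apart in thinned (0.32) and Xist-only cells (0.66).

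Shares moved most, with 54 outside their planned interval and 30 within, counting shares of cell classes and of cycling cells. Every alternative measure of cycling cells changed the UMI minimum, the thinning or the gene list, and each lay outside the planned interval. The ILC2-like share of sets 1 and 2 was 79.8% and 94.5% at resolution 0.3, 45.8% and 71.2% with 15 principal components, 56.6% and 85.2% with called doublets kept, and 63.7% and 83.7% with each set clustered by itself. In set 2 it was 81.1% with 1000 variable genes and 68.3% with at most 5% mitochondrial UMIs. The cycling cluster held 20.1% of set 1 at resolution 0.3, 22.7% at resolution 1.0, 22.0% with 15 principal components and 22.2% with called doublets kept.

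Clusters with ILC3 markers held 0% of both sets at resolution 0.3, 8.51% and 0.399% with 1000 variable genes, 12.7% and 0.373% with at most 5% mitochondrial UMIs, and 12.7% and 10.7% with each set by itself. The last of these was another group of cells, since 258 of its 377 cells were of cluster 5 and 0 of cluster 1. In set 2 they held 0.485% at resolution 1.0 and 0.0570% with 15 principal components. Clusters with low ILC2 markers held 0% of both sets at resolution 0.3 and with each set by itself, and 22.0% and 22.9% with 15 principal components. In set 2 they held 15.3% with 1000 variable genes, 8.84% with called doublets kept and 27.7% with at most 5% mitochondrial UMIs. Clusters of low UMI held 0% of set 1 with 15 principal components, 1000 variable genes, called doublets kept, at most 5% mitochondrial UMIs and each set by itself, and 0% of set 2 with 1000 variable genes and with at most 5% mitochondrial UMIs.

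Cycling cells made up 96.9% and 95.6% with at least 2 UMIs, 80.3% and 74.1% with at least 5 UMIs, 97.1% and 86.4% with no thinning, and 85.1% and 83.0% with the G2M list alone. The 8 cycling markers gave 36.4% and 8.82% thinned and 46.1% and 8.69% with no thinning, and both lists without 6 genes expressed outside the cycle gave 47.0% and 14.5%. Depth limits set 2 more, since its cells held a median of 4849 UMIs against 10666.5 in set 1, and thinning left out 1172 of its cells.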

Other observations

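The tests with the 8 cycling markers, by sex-linked RNA and of the keratin-associated genes were chosen only after the result was seen, and so was the group of cells that opens this part. A small group of cells with high Il5 appeared in set 2 at other clustering settings. It was picked as a cluster with a high median of the ILC2 markers. Il5, Il1rl1, Klrg1 and Gata3 belong to those markers, so their height follows in part from the choice, while Csf2 does not belong to them. At resolution 1.0 the group held 72 cells of set 2 (2.05%), all within cluster 4, and a cluster picked in this way appeared in 5 of the 6 alternative joint clusterings. Il5 stood at 2327 CPM in it against 192 CPM in the other cells of set 2, and Il1rl1, the gene of the IL-33 receptor, at 502 against 8.97 CPM. Klrg1 was at 178 against 2.10 CPM, Csf2 at 888 against 90.6 CPM and Gata3 at 1902 against 563 CPM. Il17rb, by contrast, was at 22.0 against 64.6 CPM. When set 2 was clustered by itself, 78 cells formed such a cluster with Il5 at 2370 CPM, and 59 of them belonged to the former group. The cluster of set 1 with the highest ILC2 markers (108 cells) had Il5 at 347 against 129 CPM and Il1rl1 at 67.5 against 15.7 CPM.

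Both cell sets held cells with Xist and cells with Y-linked RNA. In set 1, 524 cells had only Xist and 662 only Y-linked UMIs, and in set 2 the numbers were 1428 and 1186. Cells with Xist alone made up 42.4% of those with either in cluster 0 of set 1 (38.4 to 46.6%) and 53.7% in cluster 4 of set 2 (51.2 to 56.2%).

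The cycling cluster held a larger share of set 1 than of set 2, and set 1 was also the deeper set, so depth alone could account for it. With every cell thinned to 4106 UMIs, the share of cells with at least 3 UMIs of the 8 cycling markers stayed 4.13 times higher in set 1, past the bound of 2, with intervals that did not meet. This argues against depth as the whole cause. The ages of the libraries stay open as a biological explanation, untested because cells were not assigned to days, as does the sort.

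Set 2 split into cluster 4 and the heat-shock and early-response cluster 3, and the split may rest on those genes alone, which tissue digestion can induce. The cells were clustered again without 81 of the 2000 variable genes. The name pattern that chose these covered heat-shock and early-response genes, and also histone, Klf, Rgs, Rel and Socs genes. In this clustering 82.0% of the cells of cluster 3 (79.5 to 84.4%) fell into new clusters in which they outnumbered cluster 4. Of these, 692 shared a new cluster with 315 cells of cluster 4, and 129 joined one led by 424 cells of cluster 5. The bound against this explanation, 80%, lies inside that interval, so it was not passed by more than its error and the explanation stays open. The other 180 of 1001 cells fell where cluster 4 outnumbered them, 160 of them in its largest new cluster, a share (15.6 to 20.5%) below the 0.5 named in advance for those genes as the cause. No biological explanation was tested.

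The 20 genes furthest apart between the sets were also examined by sex, since they would be lost in cells of the other sex if animals of 1 sex made the difference. Taken separately in Xist-only and in Y-only cells, 20 of the 20 kept their direction with at least a 2-fold difference, above the bound of 18, which argues against animals of 1 sex as the cause. A difference between animals of the same sex was not tested. Age and a library effect stay open, since neither can be separated from the cell set.

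Keratin-associated protein genes summed to 163 CPM in set 2 and 3.11 CPM in set 1, and 1 cell held 58.4% of their 2947 UMIs in set 2.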
